A study of Equus caballus with 6 samples.

How the data were processed

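The series holds 6 one-colour CodeLink human arrays, 1 per stallion, 3 from dexamethasone and 3 from saline-treated animals. Per the labels, total RNA of minced testicular parenchyma was prepared with Tripure, and labelled cRNA made with the CodeLink manual protocol was read as Alexa-647. The scanner software, its version and its rule for flags are not given in the sources used here. The files the authors deposited give for each spot the mean intensity, the median local background, their difference, a scaled intensity and a quality flag. The deposited scaled intensity was, from the values, the background-subtracted intensity divided by 1 constant per array, so that the median of each array is 1, and it is on a linear scale that includes values below 0. The table of the whole series repeats these scaled intensities. Per the file headers there is also a signal strength, a score that equals the spot mean over the spot's own noise level. The scores were below 1 where the flag L marks a spot near background.

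Spots flagged M had no value (353 to 610 per array). Spots with the flags C, I or P (320 to 1189 per array) were treated as missing, although the files do not state what these letters mean. Saturated spots were kept. Probe names printed more than once, 94 names with 6 to 12 copies and 631 blank spots, were taken as controls and left out after background correction. Spot mean and background median were corrected with normexp (offset 50), quantile normalised between arrays and taken to log2 with limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Median spot intensity was 73.0 to 80.2 over a median background of 47 to 50, so that many probes lie close to background. Their differences are compressed by the offset.

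A probe was tested if it was above background on at least 3 of the 6 arrays and had at least 2 values per group, which left 24590 of 53423 probes. The gene table for the probes gave exactly 1 symbol to 23472 probes, several to 905 and does not list 29046, which are unnamed here. Of the tested probes 12105 have 1 symbol, covering 10604 genes. For each gene the brightest probe stood in list tests. Symbols found in the gene table of the horse assembly TB-T2T were above background on 3 or more arrays for 53.4% of probes, against 44.2% for other symbols. No probe sequences or horse genome were used here, so how well each human probe matches its horse transcript was not examined, and low signal does not show low expression.

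Groups came from the labels. Replicate numbers were given here in the order of the samples within each group and pair no stallions. The test was limma's lmFit and eBayes for dexamethasone against control without covariates, two-sided, with Benjamini-Hochberg adjustment over all tested probes. Errors of differences are limma's moderated standard errors and intervals are 95%. The 26 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes (a) up to 10 higher and 10 lower genes with the smallest p among probes with 1 symbol, non-overlapping groups and at least 1.5-fold, (b) 14 fixed genes of steroid synthesis and glucocorticoid response, and (c) the leading members of each list described. Lists were planned for limma's camera with a preset correlation of 0.01. Because camera needs complete values, which would have left few genes in some lists, its version for ranked statistics (cameraPR) was run on the moderated statistics of all tested genes. The estimated correlation and fry were run on genes with complete values, with the spots flagged C, I or P kept. Slide numbers form 2 runs, of 4 and 2 arrays, each holding both groups, and the run was used as a block in an alternative. The other alternatives were other background corrections and normalizations, the deposited scaled intensity with a floor of 0.1, other filters, the mean of a gene's probes, eBayes with trend and robust settings, array weights and leaving out each array in turn. Keeping spots flagged C, I or P was added after seeing the data.

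The test was tried on simulated data with the real probe means and with variances drawn from limma's estimated prior, over 24590 probes of the dexamethasone against control comparison. With 200 changed probes, 61.2% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes were recovered. With 20 changed probes, 0 of 7 at 1.5-fold, 4 of 7 at 2-fold and 6 of 6 at 4-fold were recovered, so that 1.5-fold changes of a small number of probes were not recovered by the adjusted test. A shift of -0.3 put on the 14 cholesterol genes gave a camera adjusted p of 8.31e-09 with 0 other lists called. The simulation left out correlation between probes and array effects. Its changes were put on the normalised log2 values, after the offset, so the shares recovered are not those for changes of the transcripts. Near background the offset compresses such changes, and their recovery was not simulated.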

Results

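Testicular parenchyma, the tissue of the seminiferous tubules and the interstitial cells between them, was taken from 6 adult stallions. After 10 days of acclimation, 3 stallions had received 0.1 mg/kg dexamethasone intravenously and 3 had received saline, and the testes were removed 12 h later. Dexamethasone is a synthetic agonist of the glucocorticoid receptor. Total RNA of each stallion was hybridised to 1 human CodeLink array, so horse transcripts were read by probes designed for human ones. Each array carried 54990 spots, of which 53423 were probes present once and treated as gene probes. Between 22690 and 25537 of these were above background per array (42.5% to 47.8%). The normalised arrays correlated with each other at 0.984 to 0.991 over the 15 pairs, which is across probes, and probes are not independent replicates. Among the 94 repeated control probes, 30 with a common start of their names were all higher in the dexamethasone stallions, by 0.35 to 0.65 on the log2 scale, a size like that of many gene differences given here. Grouped after their values were seen, they averaged 8.93 ± 0.25 against 8.41 ± 0.57 (SD, n = 3 each), with groups that overlapped (exact two-sided permutation p = 0.3). Their difference of 0.52 was 0.66 and 0.24 within the runs of slides and 0.23 without control replicate 1. Most other control probes were higher too, by less. In a second series of 32 with a common start, 31 were higher, with a mean difference of 0.09. Of the remaining 32, 22 were higher, with a mean difference of 0.01. None of the 94 passed limma's adjusted p. The number of arrays limits the precision. With 3 stallions against 3, an exact two-sided permutation test of a single gene cannot give a p below 0.1.

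The comparison of the treated with the saline stallions asked which testicular genes differ 12 h after the glucocorticoid, with the genes of steroid synthesis named in the title of the series. INSL3, a peptide hormone of Leydig cells, differed by -1.21 ± 0.23 on the log2 scale (SE) between dexamethasone and control stallions, at 9.34 ± 0.55 against 10.54 ± 0.18 (SD, n = 3 each), and the groups did not overlap. SQLE, the squalene epoxidase of cholesterol synthesis, differed by -0.62 ± 0.10 (SE), at 9.38 ± 0.11 (SD, n = 3) against 9.99 ± 0.03 in the 2 control stallions with a usable spot. GSTA3, a glutathione transferase that also acts as a ketosteroid isomerase, differed by -0.66 ± 0.16 (SE), at 8.12 ± 0.38 against 8.78 ± 0.11 (SD, n = 3 each). These 3 genes passed limma's test adjusted over the list alone, INSL3 among Leydig genes with adjusted p = 0.00389, SQLE among cholesterol genes with 0.00315 and GSTA3 among antioxidant genes with 0.0279. None of them passed over all probes tested, where limma's adjusted p was 0.999 for each, and other splits of the 6 stallions gave up to 7 genes adjusted over the list alone. Adjusted over the list alone, INSL3 missed the threshold with the mean of its probes (limma adjusted p = 0.0609), and GSTA3 without control replicate 1 (0.126), 2 (0.114) or 3 (0.0570), with background subtraction (0.114) and with the authors' values (0.0673). SQLE lacked control replicate 1 in the main setting. With the spots flagged C, I or P kept, SQLE differed by -0.50 (limma adjusted p over the list alone = 0.0293), the smallest difference among its alternatives. With the run of slide numbers as a block the log2 differences were -1.21 ± 0.21 for INSL3, -0.63 ± 0.11 for SQLE and -0.66 ± 0.17 for GSTA3 (SE). Within the first run of slides (2 stallions against 2, but only 1 control value for SQLE) they were -1.33, -0.61 and -0.79. Within the second (1 against 1) they were -0.96, -0.66 and -0.40. A second INSL3 probe differed by -0.52 ± 0.22 (SE), with groups that overlapped slightly. Without dexamethasone replicate 1 that probe differed by -0.22, and the first INSL3 probe by -0.89.

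None of the steroidogenic enzymes and carriers themselves passed the test. STAR, which moves cholesterol into mitochondria, differed by 0.01 ± 0.11, CYP11A1, the side-chain cleavage enzyme, by 0.08 ± 0.11, and CYP17A1, the 17-alpha-hydroxylase, by 0.00 ± 0.11 (log2, SE). CYP19A1, the aromatase, differed by 0.07 ± 0.12 and HSD3B2 by -0.17 ± 0.11. The 95% intervals ran from -0.25 to 0.27 for STAR, from -0.17 to 0.33 for CYP11A1, from -0.26 to 0.27 for CYP17A1, from -0.18 to 0.33 for CYP19A1 and from -0.42 to 0.07 for HSD3B2. Mean levels in dexamethasone and control stallions were 7.55 and 7.54 for STAR, 7.84 and 7.76 for CYP11A1 and 7.36 and 7.36 for CYP17A1. They were 7.71 and 7.64 for CYP19A1 and 7.14 and 7.32 for HSD3B2. The offset compresses differences close to background, so these intervals need not bound the change of the transcripts. The other STAR probes differed by -0.12 ± 0.09 and 0.19 ± 0.10 (SE). CYP17A1 had usable values on 2 arrays per group and CYP11A1 on 2 of the 3 control arrays. HSD3B2 rested on 2 dexamethasone values, 7.01 and 7.28, and differed by -0.04 without dexamethasone replicate 2 and by -0.31 without dexamethasone replicate 3. These 5 genes were the tested members of a list of 19. The list's median log2 difference was 0.01 and its adjusted p with limma's camera was 0.993, with none of the 5 past the test over all probes or adjusted over the list alone. The mean of the list was -0.00, of the opposite sign to its median. Its median was 0.02 within the first run of slides and -0.04 within the second. The probes of NR5A1 and FKBP5 were above background on 0 arrays and that of HSD17B3 on 1, so none of these was tested. HSD3B1 was read only by a probe shared with HSD3B2, above background on 0 arrays. LHCGR, the LH receptor, was at 12.20 ± 0.02 against 12.29 ± 0.11 (SD, n = 3 each), a difference of -0.08 ± 0.09 (SE).

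**Figure D1:**
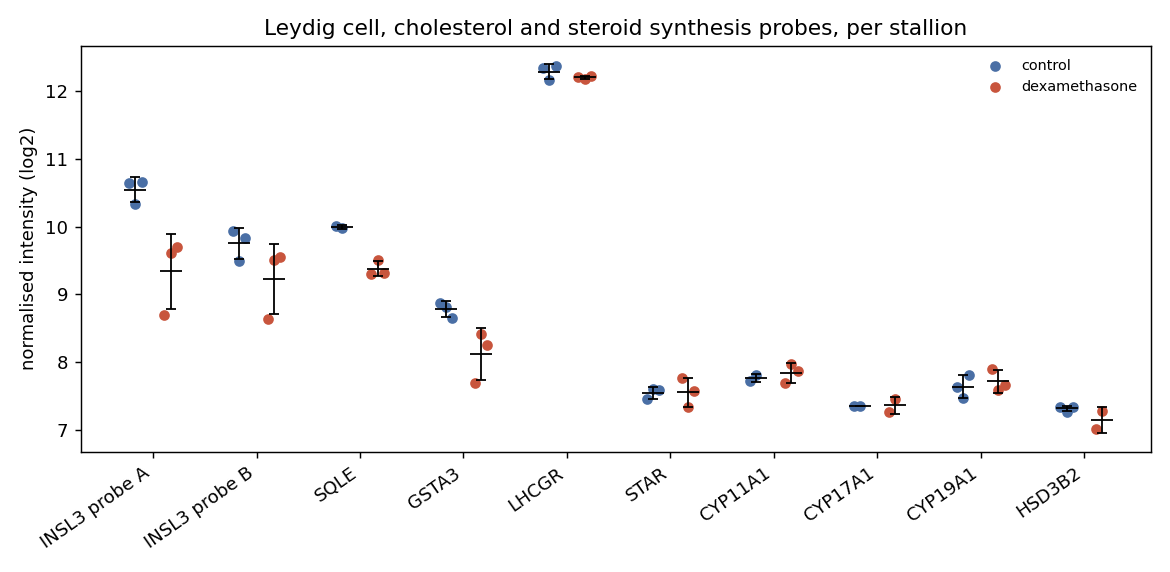
Normalised log2 intensity (y axis) of probes for Leydig cell, cholesterol, glutathione and steroid synthesis genes (x axis); each point is 1 stallion, and the bars give the group mean and SD. Both INSL3 probes, SQLE and GSTA3 have lower means in the dexamethasone stallions, while the means of STAR, CYP11A1, CYP17A1 and CYP19A1 differ by less than the larger of their group SDs.

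Over all 24590 probes tested, 1 rose past limma's adjusted p of 0.05 and 0 fell. It was a probe of ATPAF1, an assembly factor of the mitochondrial ATP synthase, which was 3.04 ± 0.25 higher on the log2 scale (SE, adjusted p = 0.00806), at 9.45 ± 0.64 against 6.40 ± 0.08 (SD, n = 3 each). It was above background in 3 of 3 dexamethasone stallions and in 1 of 3 controls, and the size of the difference depends on the background correction, at 4.36 with background subtraction. A second ATPAF1 probe, above background on all 6 arrays, differed by 0.08 ± 0.13 (SE). With the slide run as a block the first probe's difference was 3.04 ± 0.26 (limma adjusted p = 0.0274), and within the runs it was 3.19 and 2.76. The call was lost without control replicate 1 (adjusted p = 0.112) or 3 (0.0846), with background subtraction (0.0532) and with trend and robust eBayes (0.730). The next smallest adjusted p of any probe was 0.880. At an unadjusted p under 0.05 there were 808 probes, 362 higher and 446 lower, where 1229.5 would fall by chance if the p-values were uniform. Median scaling gave 1798, of which 6.17% were higher, and the authors' values gave 838, of which 26.0% were higher, against 44.8% of the 808. More were higher than lower only with cyclic loess normalization (51.4% of 821) and without control replicate 2 (53.5% of 691). The groups did not overlap for 9.27% of the probes. Chance gives 10% for probes with 6 values and a higher share for the 2258 with a missing value.

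**Figure D2:**
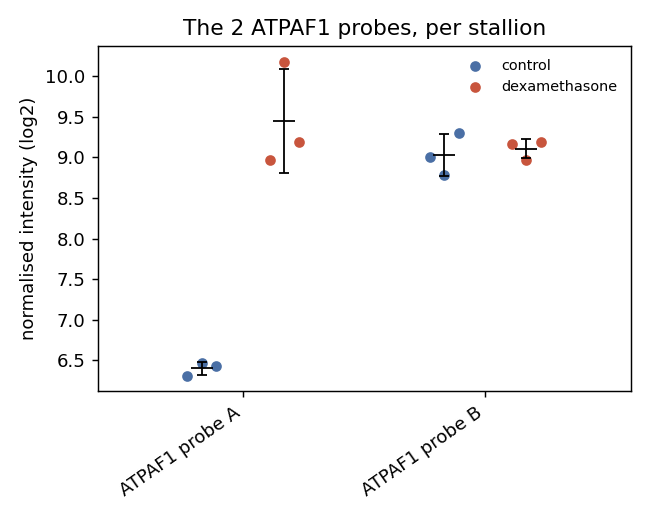
Normalised log2 intensity (y axis) of both ATPAF1 probes (x axis); each point is 1 stallion, and the bars give the group mean and SD. Probe A has a mean of 9.45 in the dexamethasone stallions and 6.40 in the controls, and probe B differs by 0.08.

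Past an unadjusted p of 0.05 and 1.5-fold there were 26 probes, 15 higher and 11 lower, of which 20 have a gene name. More were lower than higher under median scaling (9 higher and 25 lower), with background subtraction (83 and 119) and with the authors' values (77 and 151). Without each array in turn there were 45 to 64. Apart from ATPAF1 these are given as values only. Among those higher in the dexamethasone stallions, SPMIP10 differed by 0.78 ± 0.14, KRT28, a keratin, by 0.98 ± 0.20, FTMT, mitochondrial ferritin, by 0.60 ± 0.14, ENOX1 by 0.64 ± 0.19 and DUSP19, a phosphatase, by 1.03 ± 0.32 (log2, SE). ENOX1 was above background in 2 of 3 controls, and differed by 0.40 without control replicate 2 and by 1.43 with background subtraction. DUSP19 rested on 2 control values, 8.06 and 9.43, and differed by 0.35 without control replicate 1 and 1.72 without control replicate 2. SPAG17 and TSPAN3, also named by the rule on non-overlapping groups, differed by 0.78 ± 0.40 and 0.72 ± 0.46, but by 0.18 and 0.02 without dexamethasone replicate 1. The other TSPAN3 probes differed by -0.15 and -0.03. Among those lower, FAM20A differed by -0.62 ± 0.10, BCL11A, a transcription factor, by -0.71 ± 0.12, ACTN4, an actin crosslinker, by -1.08 ± 0.21, GCA by -0.94 ± 0.25 and CCDC138 by -0.72 ± 0.26, or -0.34 without dexamethasone replicate 1. CYP4F22 had usable values in 2 dexamethasone stallions, neither of them above background. With these raised, where lower, to the lowest value above background on the same array, its mean was 1.32-fold higher in the controls. That ratio compares group means and carries no error, and limma's adjusted p was 0.999. Second probes of ACTN4 and BCL11A differed by 0.01 ± 0.09 and -0.01 ± 0.08 (SE).

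The genes known to respond to glucocorticoids did not pass the test as a group. Of a list of 32 glucocorticoid-induced genes, 21 were tested, 11 lay higher and 10 lower, the median difference was 0.00 and the camera adjusted p was 0.993. TSC22D3 (GILZ) differed by 0.07 ± 0.12, PER1 by 0.00 ± 0.20 and the glucocorticoid receptor gene NR3C1 by -0.16 ± 0.19 (SE), with -0.37 to -0.01 for NR3C1 without each array in turn. Over the alternative settings TSC22D3 ranged from -0.05 to 0.20 and PER1 from -0.20 to 0.20. The PER1 probe was dim, above background in 2 of 3 stallions of each group. KLF15 differed by -0.53 ± 0.21 but was above background in 1 of 3 dexamethasone stallions and had 2 control values, 7.22 and 6.52. It differed by -0.18 without control replicate 1 and by -1.22 with the authors' values. The members with the next smallest p were FOXO1 at -0.16 ± 0.08, ZBTB16 at 0.20 ± 0.11 and CEBPD at 0.22 ± 0.13 (SE). None of these passed adjusted over the list alone. The list's median was -0.01 within the first run of slides and 0.05 within the second. Of the inflammatory genes that glucocorticoids repress, 14 were tested with a median of 0.01 (adjusted p = 0.975), and IL1A was the member with the smallest p, at 0.36 ± 0.12. Adjusted over the list alone, IL1A did not pass in the main setting (limma adjusted p = 0.202). It passed with the run of slides as a block and without control replicate 3.

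No list of the 26 passed camera's adjusted p of 0.05. The smallest, 0.235, was that of cholesterol synthesis and supply, with 11 of its 14 tested members lower and a median of -0.08. Its unadjusted p was 0.00902, and with an estimated correlation its adjusted p = 0.997. Besides SQLE, MVK differed by -0.34 ± 0.11 and DHCR7 by 0.19 ± 0.08 (SE), or 0.41 with background subtraction. The list's median was -0.16 within the first run of slides and 0.02 within the second. limma's fry, which asks whether a list's genes differ in either direction, gave an adjusted mixed p of 0.000413 for this list and 0.00102 for the peritubular myoid list, whose 6 tested members include MYLK at -0.22 ± 0.08 and CALD1, above background in 1 of 3 dexamethasone stallions, at -0.20 ± 0.10, or -0.52 with background subtraction. Another split of the 6 stallions gave 4 lists past this mixed p, against 2 for the real one, while the smallest adjusted mixed p of any split was the real one's 0.000413, against 0.00391 for the next. fry gave no adjusted p below 0.522 for differences in 1 direction.

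No list of cell type markers passed camera. Leydig cell genes had a median of -0.06 over 10 tested members (adjusted p = 0.914), Sertoli cell genes -0.02 over 15 (0.993), spermatogonia 0.03 over 11 (0.914), spermatocytes -0.02 over 17 (0.993) and spermatids 0.01 over 17 (0.914). In the Sertoli list CLDN11, a tight junction gene, differed by 0.48 ± 0.13, and in the spermatid list TEKT2 differed by 0.34 ± 0.14 (SE), or 0.19 without dexamethasone replicate 2. ZPBP, of the same list and above background in 1 of 3 dexamethasone stallions, differed by -0.21 ± 0.08 (SE), or -0.56 with background subtraction. Among spermatocyte genes MSH5 differed by -0.20 ± 0.09. The medians were -0.09 for peritubular myoid, -0.08 for endothelial, 0.05 for macrophage, -0.02 for lymphocyte, 0.11 for erythrocyte, -0.04 for fibroblast and -0.01 for duct epithelial markers, with camera adjusted p between 0.914 and 0.993. The remaining lists had medians of -0.03 for hormone receptors, -0.03 for LH and cAMP signalling, -0.05 for the IGF and insulin axis, -0.11 for chaperones, 0.00 for immediate early genes, 0.01 for clock genes, -0.00 for apoptosis genes, -0.04 for antioxidant genes, -0.02 for ribosomal proteins and 0.04 for oxidative phosphorylation, again with adjusted p from 0.914 to 0.993. In the receptor list GNRHR, above background in 1 of 3 controls, differed by 0.29 ± 0.09, or 0.78 with background subtraction, and in the chaperone list HSPA8 differed by -0.22 ± 0.10 (SE), or -0.15 without dexamethasone replicate 1. In 8 of the 26 lists the median, the mean and the direction of the test differed in sign, among them the steroid synthesis and glucocorticoid-induced lists. HSPE1 differed by -1.89 ± 0.99 (SE) over 2 dexamethasone values that lay far apart, at 12.6 and 8.13, and by 0.35 without dexamethasone replicate 3.

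**Figure D3:**
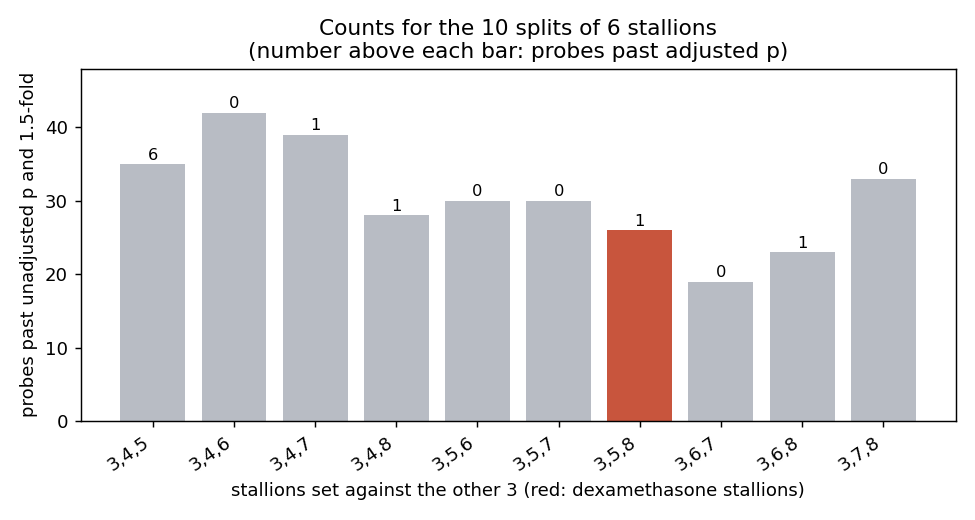
Number of probes past an unadjusted p of 0.05 and 1.5-fold (y axis) for each of the 10 ways to set 3 of the 6 stallions against the other 3 (x axis); the red bar is the dexamethasone against control split and the number above each bar counts probes past adjusted p. The real split has 26 and 1, and the other splits reach 42 and 6.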

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

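The alternative settings here were planned before the data were examined, except the keeping of spots flagged C, I or P. The use of cameraPR in place of camera, and the counts over other splits of the stallions except that for fry's mixed p, were settled after the data were seen. Probes past adjusted p numbered 1, and 0 with background subtraction, with a filter of all 6 arrays and with trend and robust eBayes, and 0 to 3 without each array in turn (0 without control replicate 1 or 3, 2 without dexamethasone replicate 1, 3 without control replicate 2). Probes past unadjusted p and 1.5-fold numbered 26, and 202 with background subtraction, 228 with the authors' values and 41 with no filter, and 45 to 64 without each array in turn. Dropping the filter raises the probes tested to 52902. The ATPAF1 probe is not tested under the filter of all 6 arrays. Other causes were not tested. Under median scaling 26.5% of the 34 such probes were higher, against 57.7% in the main setting, and 41.1% with background subtraction and 33.8% with the authors' values. Genes past adjusted p over the list alone numbered 3, and 5 with median scaling, and 2 to 6 without each array in turn. INSL3 kept this in 17 of 18 alternatives, GSTA3 in 13 of 18 and SQLE in all 17 that tested it. No list passed in camera under any of the alternatives run, or in fry's test of 1 direction, which was run in 1 setting. There were 63 changes of sign among 519 values, none of a called list. ATPAF1 lost its call with background subtraction (adjusted p = 0.0532), with trend and robust eBayes (0.730), without control replicate 1 (0.112) and without control replicate 3 (0.0846), in limma with a range of 2.16e-05 to 0.730 over its alternatives. Calls of HSPE1 without dexamethasone replicate 1 (-4.14) and of DUSP19 without control replicate 2 (1.72) each rested on 1 value in a group. Both probes are included in the counts given for those settings. The 120 named genes kept their side of the threshold in 2119 of 2125 values, with 48 changes of sign, 4 of them for STAR and 6 for CYP17A1. The median of the steroid synthesis list ranged from -0.06 to 0.03 and that of the glucocorticoid-induced list from -0.06 to 0.05. The scan date was not run as a block because file names give 1 date. Genes not tested under a setting, and probe counts under the mean of a gene's probes, have no value. No paired analysis was possible because the labels give each stallion a number of its own, and the replicate numbers used here only follow the order of the samples within a group. Signal close to background limits all dim probes.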

Other observations

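The tests of the ATPAF1 and INSL3 patterns, the count of probes with a gap, and the counts over splits other than that for fry's mixed p were settled only after their results were seen.

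Some probes split the stallions sharply without regard to treatment. Of 22332 probes with 6 values, 67 had a gap of at least 1 on the log2 scale between neighbouring stallions, and in 55 of these 1 stallion stood apart. In 5 the gap parted 3 stallions from 3, and 1 of those followed treatment, the ATPAF1 probe. EIF4EBP1, chosen after its values were seen, was low in control replicate 3 alone by both of its probes, with gaps of 3.24 and 3.61.

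The ATPAF1 probe was 3.04 higher in the dexamethasone stallions. A change of the ATPAF1 transcripts that both probes report is argued against by the second probe, whose upper 95% limit was 0.37. A signal particular to the first probe may account for it, since the second probe differed by 0.076. Whether that is a sequence variant carried by these stallions, an isoform or another transcript was not tested, and an isoform that responds to treatment stays open.

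INSL3 differed by -1.21 between dexamethasone and control stallions. A lower share of Leydig cells would lower their other genes by a like amount. The median of the 14 other tested Leydig and steroid synthesis genes was -0.0023 (bootstrap 95% interval -0.07 to 0.08). That of the 10 with a signal above the median was -0.04 (-0.07 to 0.07). The bootstrap resampled genes read on the same arrays, so its intervals leave out the spread between stallions. Within that limit, these medians argue against a lower share for the first INSL3 probe, with an upper limit of -0.70. They leave it open for the second probe, whose upper limit of -0.026 lies within both intervals. The comparison takes the human probes to report the horse genes, and several of these genes are also expressed by other testicular cells. Whether the difference is particular to 1 probe cannot be told apart from a change of the transcript, because the second probe's upper limit reached 0.15 without control replicate 1, 0.13 without control replicate 3 and 0.07 without dexamethasone replicate 1. A response of INSL3 to dexamethasone stays open and may be a hypothesis to test with horse-specific assays.

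With 6 stallions there are 10 splits into 3 and 3, too few for a share under 0.05. The counts of splits that gave as many include the real split and those with a larger result. Probes past adjusted p numbered 1 for the real split and up to 6 for another, and 5 of 10 splits gave as many. Probes past unadjusted p and 1.5-fold numbered 26 against a highest other of 42, and 8 splits gave as many. Genes past adjusted p over the list alone numbered 3 against 7, and 5 splits gave as many. Lists past fry's adjusted mixed p numbered 2 against 4, and 2 splits gave as many. The split that called 6 probes set stallions 3, 4 and 5 against 6, 7 and 8, which follows the order of the stallion numbers and is not the split by slide run. More calls than the real split gave can point to a structure of the samples, but this was the highest of the other splits and no such structure was tested.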
